A study of Caenorhabditis elegans with 6 samples.

How the data were processed

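RNA abundance was measured by sequencing in whole young adult *Caenorhabditis elegans*, with 3 libraries of the wild-type strain N2 and 3 of the *blmp-1(s71)* mutant. Per the labels' protocols, bleached embryos gave synchronized first-stage larvae that were raised on agar plates to young adulthood, RNA was extracted with TRIzol, and libraries were made with TruSeq RNA kits. The groups and replicate numbers were taken from the sample titles, and the series' design text calls the libraries biological replicates. The labels name no batch, no sequencing date and no paired design.

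The authors deposited for each library, per the file headers, 1 CPM value (reads scaled to a fixed total over genes) and 1 TPM value (the same with a correction for gene length) for each of 47157 gene IDs. The deposited CPM and TPM each summed to the same total in every library, so no scaling between libraries had been applied. Trimmomatic 0.36, HISAT2 2.1.0, featureCounts 1.6.3 and DESeq2 1.22.0 are named, with no role or order, per the submitters' processing notes. The genome build, the annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Values of overlapping genes and of near-identical genes, among them many collagens, the vitellogenins *vit-3*, *vit-4* and *vit-5*, the major sperm proteins and the *cnc* peptides, are therefore uncertain as to which copy the reads came from. For 11 genes the deposited symbol had been turned into a date by a spreadsheet, and the reference symbol of the same WormBase ID was used instead. Of the gene IDs, 43985 matched the reference gene table.

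The test first planned was edgeR's quasi-likelihood test on counts. Since the deposited values were CPM, limma 3.58.1 in R 4.3.3 on log2(CPM + 1) took its place as the main test. The CPM were divided by TMM factors between 0.813 and 1.21, and genes with a CPM of at least 1 in at least 3 libraries were kept, which left 13756 genes. The fit had the group as its only term, with limma's mean-variance trend and robust moderation, and Benjamini-Hochberg adjustment at 0.05. These settings were chosen after the files had been looked at. A fold change is on the log2(CPM + 1) scale, which understates changes of genes with low CPM. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. The gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

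In each library the CPM values were whole multiples of the value of 1 read. Within a tolerance of 0.01 reads, 100% of the nonzero values in each of the 6 libraries came out whole. The recovered totals ran from 5255125 to 15218178 reads, and 3 reads corresponded to between 0.197 and 0.571 CPM. Intervals and floors from reads cover counting error only. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives and called 2823 and 3779 genes.

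For the 41 gene lists, camera asked whether a list's genes stood apart from the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. The same test with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. The named genes were *blmp-1*, the 8 largest rises and 8 largest falls among called genes with a mean log2 value of at least 2 and no overlap between the groups, up to 4 called members of each described list by smallest adjusted p (or, with none called, the member with the highest mean), and *dre-1*, *lin-29*, *daf-12*, *bed-3* and *unc-5*, which earlier work links to *blmp-1*. Gene positions are from the WBcel235 annotation, which may differ from the build the authors used.

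The first alternatives were DESeq2 and limma-voom, other scalings, no filter on low values, a replicate block, each library left out in turn, and the removal of dominant genes or of sperm and oocyte genes. Added after the data were seen were edgeR on the recovered reads with and without a replicate block, other pseudocounts (0.1, 0.5 and 2), edgeR's own filter, TPM, the removal of ribosomal RNA or of both replicate-1 libraries, a threshold of 0.01, an oocyte covariate, and leaving out each library with edgeR and with DESeq2. The fit was tested on 5 sets of simulated counts with 200 changed genes each, drawn from the wild-type means and the estimated spread for this comparison, over a mean of 12947.6 genes. It recovered 30.4% of the genes changed 2-fold and 95.8% of those changed 4-fold, with 4.75% of all calls false. These sets differ from the real libraries, where far more genes were called and the count hung on single libraries. The 4.75% is therefore not an error rate for the real calls. The table of the whole series was not used, because the files of the single libraries held the values needed.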

Results

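The series compared young adult wild-type animals with *blmp-1(s71)* mutants, in 3 libraries each. *blmp-1* encodes a zinc finger transcription factor of the BLIMP1 family with roles in developmental timing, the cuticle and gonad migration. The comparison asks which transcripts differ in abundance in whole young adults when *blmp-1* is mutated. Wild-type libraries 1 to 3 held 5255125, 13319362 and 15218178 reads on genes, and mutant libraries 1 to 3 held 6586154, 13711720 and 9893919. Both replicate-1 libraries had the fewest reads and the highest share of ribosomal RNA, 4.10% in wild type and 4.69% in the mutant against 0.866% to 1.32% in the other libraries.

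*blmp-1* (WBGene00003847, chromosome I, 10409302 to 10414773 on the plus strand in WBcel235) was present in every library. Its reads were 61, 130 and 165 in the wild-type libraries and 157, 215 and 92 in the mutant libraries. The scaled level was 12.1 ± 2.20 CPM in wild type and 14.5 ± 6.87 CPM in the mutant (SD, n = 3), with a log2 fold change of 0.16 (SE 0.32) and an adjusted p of 0.697 in limma. The nature of the s71 lesion is not given in the labels, so the level of the transcript does not check the genotype.

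In the mutant, the cuticle collagen *col-124* nearly vanished, the abundant cuticle collagens *col-139*, *col-129* and *col-81* fell, and the collagen *col-176*, the fatty acid and retinol binding gene *far-3* and the antimicrobial peptide gene *cnc-2* rose. Of the lists fixed beforehand, 19 of 58 molting genes and 12 of 30 FMRFamide-like neuropeptides rose, and 16 of 26 oocyte genes and 17 of 32 germline genes fell (each list with adjusted p = 0.576 with an estimated correlation). The mean of each of these 4 lists lay nearer to wild type in mutant library 3 than in the other mutant libraries. limma with Benjamini-Hochberg adjustment called 3061 of 13756 genes at an adjusted p under 0.05, of which 1216 were higher and 1845 lower in the mutant, and 1135 differed at least 2-fold. Of the tested genes, 48.6% had no overlap between the groups. For a single gene chance gives 10%, but genes move together, so this is no chance level for the share. The number of calls hung on single libraries: 2907 of them had an adjusted p between 0.03 and 0.05, and 38 had one under 0.01. With limma, leaving out wild-type library 1, 2 or 3 left 259, 163 or 200 calls, leaving out mutant library 1 or 2 left 42 or 38, and leaving out mutant library 3 gave 5077. Called in the same direction with every library left out in turn were 31 genes, 23 higher and 8 lower. The share of calls that were higher was 39.7%, and it was 60.8% with upper-quartile scaling, 94.2% with library size alone and 87.3% with the deposited TPM. The median log2 fold change of all genes was 0.07 here and 0.18, 0.35 and 0.30 under those settings, so directions are relative to the TMM scale.

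**Figure D1:**
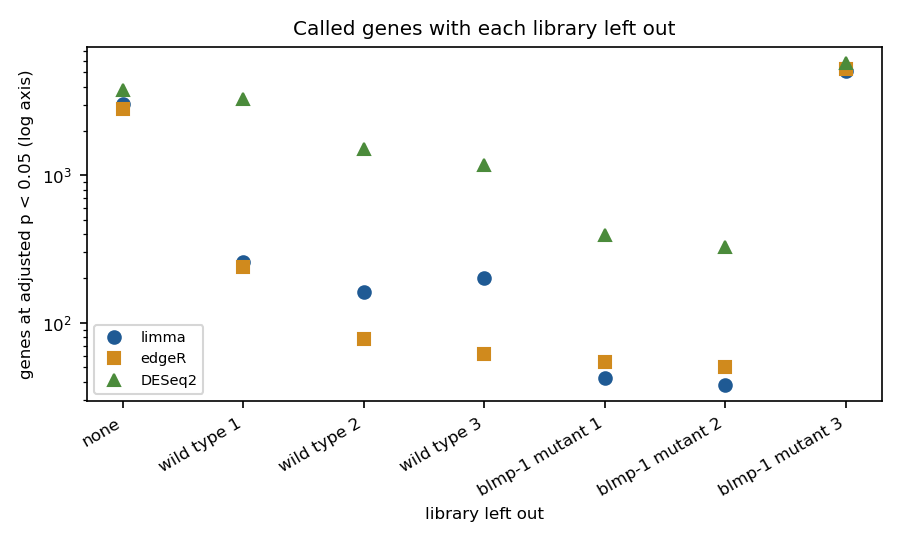
Number of genes at an adjusted p under 0.05 (log axis) with all 6 libraries and with each library left out, for limma, edgeR and DESeq2 (1 point per fit). limma called 3061 genes with all libraries, 38 without mutant library 2 and 5077 without mutant library 3.

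The largest change of all was the fall of *col-124* (WBGene00000698, chromosome IV, 10216451 to 10217617 in WBcel235), from 5136 ± 226 CPM in wild type to 59.2 ± 6.10 CPM in the mutant, a log2 fold change of -6.42 (SE 0.20, limma adjusted p = 3.81e-09). Its reads numbered 22980, 64827 and 68528 in the wild-type libraries and 434, 1065 and 559 in the mutant libraries. It overlaps *qns-1*, looked up after the values were seen, whose log2 fold change was -0.42 (limma adjusted p = 0.148). The collagens *col-139* (1621 ± 344 to 388 ± 151 CPM), *col-129* (2167 ± 720 to 522 ± 186 CPM) and *col-81* (1362 ± 510 to 289 ± 110 CPM) fell by 2.12, 2.06 and 2.24 on the log2 scale. Lower-level collagens *col-137* and *col-88* fell by 2.25 and 3.28, and *col-88* was called in none of the fits with a library left out. *acdh-2*, an acyl-CoA dehydrogenase gene, fell by 2.93 (SE 0.49), and the small gene *F54D8.10* fell by 2.07 (SE 0.28).

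*ZK970.7* rose most, from 1.53 ± 0.928 to 46.9 ± 16.7 CPM, a log2 fold change of 4.26 (SE 0.36, limma adjusted p = 0.000594). It overlaps *gcy-5*. The collagen *col-176* rose by 4.14 (SE 0.41), from 4.25 ± 2.87 to 86.5 ± 33.4 CPM. *far-3*, which encodes a fatty acid and retinol binding protein and overlaps *far-5*, rose by 3.46 (SE 0.35), from 24.1 ± 11.5 to 257 ± 56.3 CPM. *F57H12.6*, *C42D4.3* and *C45B2.2* rose by 3.27, 3.15 and 2.99, and the peptide genes *nlp-34* and *cnc-2* by 3.14 and 2.66. These 16 genes were picked among called genes with a mean log2 value of at least 2 and no overlap between the groups. Of them, *ZK970.7*, *col-176*, *far-3*, *C45B2.2*, *cnc-2*, *col-124*, *col-139*, *F54D8.10* and *col-129* stayed called with every library left out in turn.

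**Figure D2:**
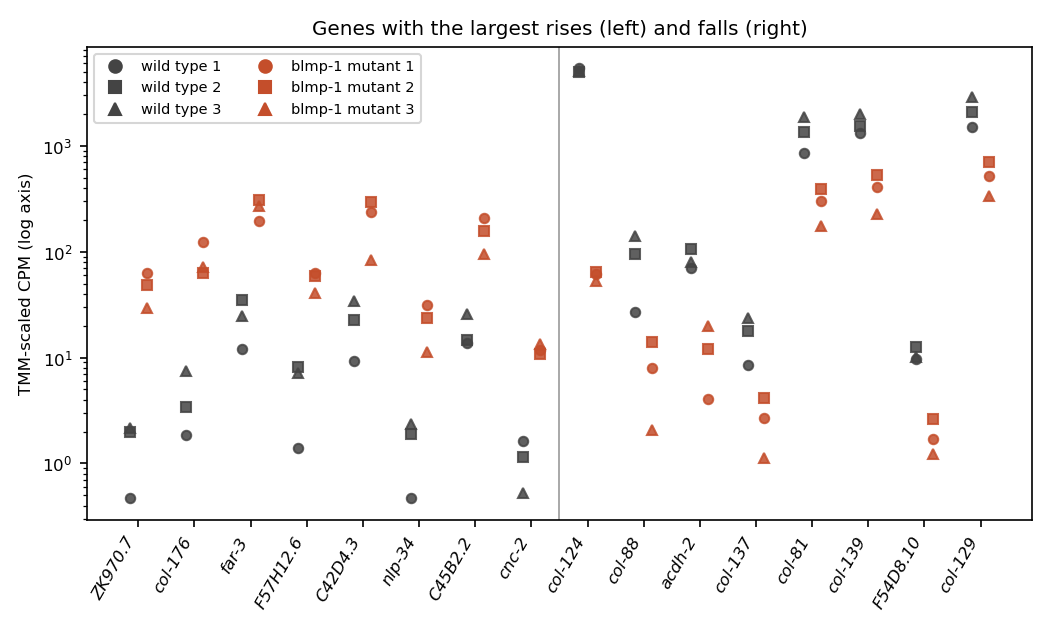
TMM-scaled CPM (log axis) of the 8 largest rises and 8 largest falls among called genes with a mean log2 value of at least 2 and no overlap between the groups. There is 1 point per library, wild type in grey and mutant in orange. By this choice the 3 mutant libraries lie on one side of the 3 wild-type libraries in each gene. *col-124* lies near 5136 CPM in wild type and near 59.2 CPM in the mutant.

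Among 133 tested cuticle collagens, the structural proteins of the worm's exoskeleton, 17 rose and 10 fell, and 106 did not pass the test. Adjusted over the list alone, 17 rose and 8 fell. The list's median was 0.57 and camera placed it higher (adjusted p = 0.0159, and adjusted p = 0.706 with an estimated correlation). The median was 0.21 without mutant library 1 (camera adjusted p = 0.204) and 0.11 without both replicate-1 libraries (camera adjusted p = 0.711). Without mutant library 3 it was 0.92 (camera adjusted p = 3.09e-05). The list's mean per library, relative to wild type, was 0.91, 0.66 and -0.31 in mutant libraries 1, 2 and 3. Of the 6 furrow collagens, which form the ring-shaped grooves of the cuticle, all had positive log2 fold changes and *dpy-2* rose, by 1.86 (SE 0.52), while 5 rose when adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.576 with an estimated correlation). The furrow list lay at 2.78, 1.87 and 0.78 in mutant libraries 1, 2 and 3. In wild-type libraries 1, 2 and 3 it lay at -0.77, -0.15 and 0.92, so the groups overlapped. Its genes moved nearly as one, with an estimated correlation of 0.96. Of 6 adult cuticle collagens, *col-19* fell by 0.87 (SE 0.22) and 5 did not pass, also when adjusted over the list alone. The adult list's median was 0.19 while camera placed it lower (adjusted p = 0.807). Of 12 collagen processing enzymes, *dpy-31*, a procollagen protease, rose by 1.07, *dpy-18*, a prolyl 4-hydroxylase subunit, by 0.88 and *bli-3*, a dual oxidase, by 0.72, and 4 rose and 1 fell when adjusted over the list alone. For the collagen processing enzymes, 4 rose with upper-quartile scaling, 6 with library size alone and 7 with TPM, and in these 3 settings none fell. On the TMM scale the peroxidase *skpo-1* fell by 0.83 (camera adjusted p = 0.0244 for the list, and adjusted p = 0.576 with an estimated correlation).

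Genes of molting and the apical matrix rose, 19 of 58, and *ptr-2* fell by 1.16, with a median of 0.96. Adjusted over the list alone, 35 rose and 1 fell. Among them *ptr-22*, of the Patched-related family, rose by 1.85 (SE 0.27) and was called with every library left out, *ptr-8* and *mlt-3* rose by 1.17 and 1.28, and *let-653* rose from 7.10 ± 2.09 to 18.1 ± 3.26 CPM. The list's camera adjusted p was 9.97e-11, and its adjusted p = 0.576 with an estimated correlation. Mutant libraries 1, 2 and 3 lay 1.47, 1.08 and 0.47 above the wild-type mean. Of 31 hedgehog-related genes, secreted proteins that often cycle with the molts, 6 rose and *wrt-8* fell by 0.79, with equal counts adjusted over the list alone, and *grl-4* (1.44), *grl-10* (1.31), *grl-22* (1.41) and *grd-1* (1.64) were among those that rose (camera adjusted p = 0.00174, and adjusted p = 0.631 with an estimated correlation). The hedgehog-related list lay at 1.29, 0.99 and 0.037 in mutant libraries 1, 2 and 3, and at 0.37 in wild-type library 3. Of 15 seam and epidermis genes, 6 rose and 2 fell, and 8 and 2 adjusted over the list alone. *fkb-3* rose to 70.8 ± 12.4 CPM, *eff-1*, the cell fusion protein, and *rdy-2* rose by 1.18 and 0.88, and *lin-26*, an epidermal fate regulator, and *egl-18* both fell by 0.92 (camera adjusted p = 0.00447, and adjusted p = 0.576 with an estimated correlation).

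Of 20 regulators of developmental and molt timing, 4 rose, also when adjusted over the list alone, and none fell. They were *nhr-85* (1.75 ± 0.199 to 5.02 ± 1.61 CPM), *lin-29*, *grh-1* (1.09) and *dre-1*. *lin-29*, the terminal regulator of the larval to adult switch, rose by 0.95 (SE 0.28, limma adjusted p = 0.0371), and *dre-1*, an F-box protein that acts on BLMP-1, by 0.75 (SE 0.25, limma adjusted p = 0.0477). The nuclear receptor *daf-12* had a log2 fold change of 0.41 (SE 0.32), *bed-3* of -0.20 (SE 0.38) and the netrin receptor *unc-5* of 0.36 (SE 0.23), and none of the 3 passed the test (limma adjusted p = 0.324, 0.690 and 0.224). Of 10 genes of distal tip cell migration, *lin-29*, *dre-1* and the netrin *unc-6* (0.77) rose, and 3 rose and 1 fell when adjusted over the list alone. camera placed both lists higher (adjusted p = 0.0197 and 0.0478, and adjusted p = 0.576 for both with an estimated correlation). Without mutant library 1 the camera adjusted p were 0.163 and 0.164. The timing and distal tip lists lay at 0.13 and 0.19 in mutant library 3, against 0.098 and 0.25 in wild-type library 1. *lin-29*, *dre-1*, *nhr-85*, *grh-1* and *unc-6* were each called in 1 of the 6 fits with a library left out.

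Of 16 epidermal antimicrobial peptides, 11 rose, and *nlp-24* and *nlp-26* fell by 0.72 and 0.73, also when adjusted over the list alone, with a median of 1.64. *cnc-2*, *cnc-3* and *cnc-7* rose by 2.66 (SE 0.28), 2.05 (SE 0.25) and 1.87 (SE 0.26) and stayed called with every library left out in turn. Mutant libraries 1, 2 and 3 lay 1.52, 1.53 and 1.03 above wild type (camera adjusted p = 9.08e-06, and adjusted p = 0.576 with an estimated correlation). Of 12 genes of the cuticle damage and osmotic response, *nlp-34*, *nlp-29* (2.06), *hmit-1.1* (1.05), *osm-11* (0.70) and *sta-2* (0.86) rose and none fell, and 8 rose when adjusted over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.576 with an estimated correlation). Both lists hold *nlp-29* and *nlp-34*. With a library left out, *nlp-34* was called in 5 of 6 fits, *nlp-29* in 4, *hmit-1.1* in 1 and *osm-11* in 0. Of 18 fungus-induced peptides, *fip-6* (2.24) and *fip-5* (1.59) rose and *fipr-13* fell from 12.6 ± 1.27 to 4.99 ± 1.66 CPM, and the counts were equal when adjusted over the list alone (camera adjusted p = 0.779). Of 90 C-type lectins, 12 rose and *clec-5*, *clec-87*, *clec-88* and *clec-91* fell by 0.77 to 1.43, 10 and 2 adjusted over the list alone, with *clec-146* (1.79), *clec-210* (1.68), *clec-70* (1.43) and *clec-17* (1.18) rising (camera adjusted p = 0.0624). Of 25 lysozymes and saposin-like genes, *lys-7* and *ilys-3* rose by 1.40 and 1.14, also adjusted over the list alone (camera adjusted p = 0.179).

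Genes of the oocyte and eggshell fell, 16 of 26, with a median of -1.40, and 21 fell when adjusted over the list alone. The germline RNA-binding proteins *pie-1* and *mex-6* fell by 1.28 and 1.36, the chitin synthase *chs-1* by 1.45 and *egg-3* by 1.27. *mex-6* went from 310 ± 25.8 to 132 ± 72.8 CPM, with 110, 73.5 and 214 CPM in mutant libraries 1, 2 and 3. As a list, mutant libraries 1 and 2 lay at -1.54 and -1.96 and mutant library 3 at -0.41 (camera adjusted p = 3.94e-09, and adjusted p = 0.576 with an estimated correlation). With library size alone 8 fell and with the deposited TPM 3 fell in the oocyte and eggshell list. Of 32 genes of the germline and meiosis, 17 fell and 29 did when adjusted over the list alone, with a median of -0.87. *deps-1*, *zim-3*, *daz-1* and *mes-6* fell by 1.19, 0.95, 1.16 and 0.95 (camera adjusted p = 2.48e-09, and adjusted p = 0.576 with an estimated correlation). With library size alone 6 and with TPM 4 of the germline and meiosis list fell. The germline and meiosis list lay at -0.93, -1.19 and -0.47 in mutant libraries 1, 2 and 3.

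Of 86 sperm genes, 9 rose and *spe-39* fell by 0.71, 3 and 0 when adjusted over the list alone, with a median of 0.42. *fer-1*, *spe-49* and *spe-19* rose by 1.55, 1.32 and 1.12 (camera adjusted p = 7.25e-07, and adjusted p = 0.576 with an estimated correlation). *fog-3*, which directs germ cells to the sperm fate, rose by 2.41 (SE 0.27), from 1.87 ± 0.649 to 14.1 ± 2.46 CPM. Of the 7 tested genes in the list of male tail and sex it was the 1 called (1 adjusted over the list alone, camera adjusted p = 0.265). The 6 vitellogenins, yolk proteins of the adult intestine, had a median of -1.64, and limma called 0 of them, with 3 at an unadjusted p under 0.05 (0 called when adjusted over the list alone, 0 by edgeR and 3 by DESeq2). They took 13.5%, 4.39% and 4.92% of the reads in wild-type libraries 1 to 3 and 4.58%, 3.69% and 5.95% in the mutant libraries. *vit-6*, the most abundant, had a log2 fold change of -0.59 (SE 0.55). camera placed the list lower (adjusted p = 0.0129, and adjusted p = 0.576 with an estimated correlation). Of 10 early zygotic genes limma called 0, with 1 at an unadjusted p under 0.05 and 0 by edgeR and by DESeq2, and *sdz-27* stood at -0.24 (camera adjusted p = 0.243).

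**Figure D3:**
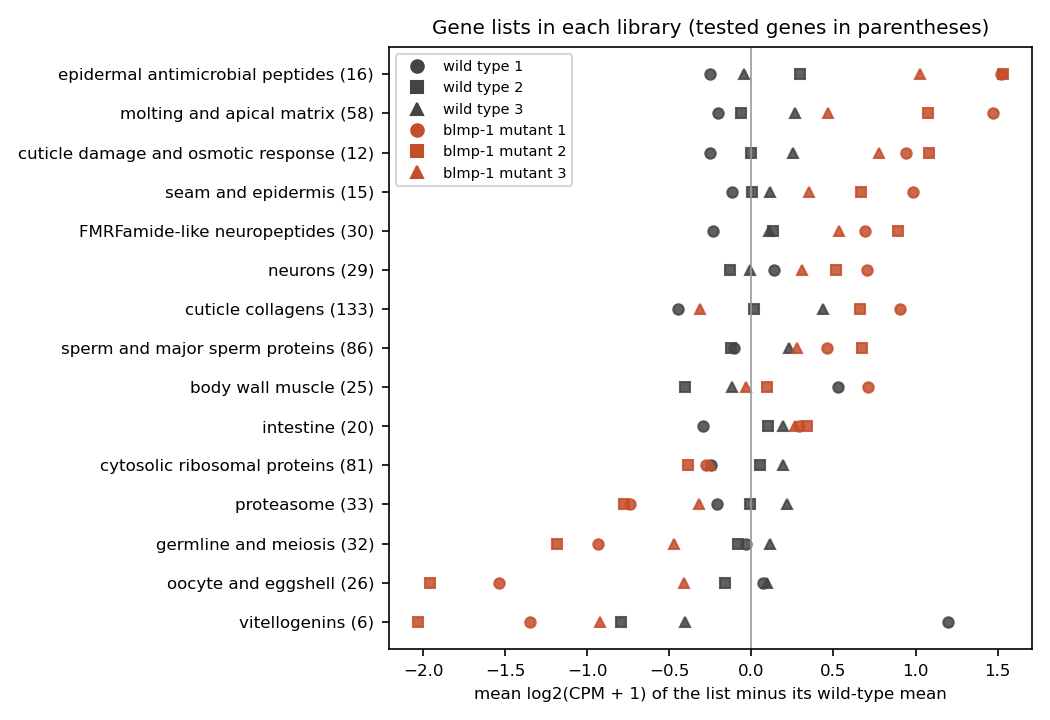
Mean log2(CPM + 1) of each of 15 gene lists minus its wild-type mean, with 1 point per library and the number of tested genes in parentheses. Mutant library 3 (orange triangle) lies at -0.41 for oocyte and eggshell genes, against -1.54 and -1.96 in the other mutant libraries, and at 1.03 for epidermal antimicrobial peptides, against 1.52 and 1.53.

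Among tissue markers, 12 of 30 FMRFamide-like neuropeptides rose and none fell, with a median of 0.77, and 23 rose when adjusted over the list alone. *flp-18*, *flp-15*, *flp-11* and *flp-1* rose by 1.15, 1.09, 0.97 and 0.84 (camera adjusted p = 2.25e-07, and adjusted p = 0.576 with an estimated correlation). Of 29 neuronal genes 6 rose, 10 when adjusted over the list alone, among them *snt-4* (0.81), *sbt-1* (0.79), *unc-9* (0.84) and *egl-21* (0.70), with camera adjusted p = 0.000208 and adjusted p = 0.576 with an estimated correlation. Of 20 intestinal genes, *pgp-1*, a P-glycoprotein transporter, rose by 1.61 (58.2 ± 4.59 to 180 ± 18.4 CPM) and *mtl-1*, a metallothionein, by 1.20, also when adjusted over the list alone (camera adjusted p = 0.102). Of 24 pharyngeal genes *phat-6* rose by 0.79 and 0 passed when adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.650 with an estimated correlation). The pharynx list lay at 1.11, 0.49 and -0.19 in mutant libraries 1, 2 and 3. limma called 0 of 25 body wall muscle genes, with 3 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2, and *unc-54*, a myosin heavy chain, stood at 0.27 (SE 0.65, camera adjusted p = 0.202 for the list).

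Of 54 cytochromes P450, 12 rose and 3 fell, 13 and 3 adjusted over the list alone. *cyp-32A1* and *cyp-13A11* rose by 1.52 and 1.24, and *cyp-31A3*, *cyp-31A5* and *cyp-31A2* fell by 1.34, 1.33 and 1.14 (camera adjusted p = 0.00452, and adjusted p = 0.576 with an estimated correlation). Of 54 glucuronosyltransferases, 7 rose and 4 did when adjusted over the list alone, among them *ugt-16* (1.29) and *ugt-55* (0.99), with camera adjusted p = 0.00517 and adjusted p = 0.576 with an estimated correlation. Of 163 nuclear hormone receptors, 12 rose and *nhr-181* and *nhr-66* fell by 0.84 and 0.75, and 0 passed when adjusted over the list alone, with *nhr-178*, *nhr-130* and *nhr-3* rising by 1.21, 0.99 and 0.94 (camera adjusted p = 5.46e-06, and adjusted p = 0.576 with an estimated correlation). Of 33 proteasome subunits, *pas-4*, *pas-1* and *rpn-5* fell by 0.75, 0.74 and 0.78 and 29 fell when adjusted over the list alone (camera adjusted p = 6.72e-08, and adjusted p = 0.576 with an estimated correlation). With library size alone and with TPM 0 of the proteasome list were called by limma, against 11 with RLE scaling. The proteasome list lay at -0.74, -0.77 and -0.32 in mutant libraries 1, 2 and 3. Of 81 cytosolic ribosomal proteins, *rpl-11.1* and *rpl-25.2* fell by 0.99 and 0.78, and the median of -0.32 turned to 0.01 with library size alone (0 adjusted over the list alone, camera adjusted p = 0.000208, and adjusted p = 0.638 with an estimated correlation). With library size alone 1 of the cytosolic ribosomal proteins rose and 0 fell, and with TPM 3 rose and 1 fell.

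camera with the preset correlation called 23 of the 41 lists, 17 higher and 6 lower, and with an estimated correlation it called 0, with 0 at an unadjusted p under 0.05. fry called 0, with 15 at an unadjusted p under 0.05. The same preset test called 13 to 21 lists for other splits of the 6 libraries into 3 and 3, against 23 for the real split. Each of those splits mixes both genotypes within its groups and keeps part of the genotype difference, so it is no measure of chance. Where a list falls outside the naming rule's 4 members, the members added to complete a small count were chosen after their values were seen.

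Over all 13756 tested genes 1216 were called higher and 1845 lower, 22.3% together. In most of the 41 lists the called members, both directions together, come to less than that share. Among these are cuticle collagens, furrow collagens, heterochronic and molt timing, neurons, sperm and major sperm proteins, glucuronosyltransferases and C-type lectins. So are nuclear hormone receptors, proteasome, cytosolic ribosomal proteins and F-box and MATH/BTB. Their counts of calls in both directions together do not set these lists apart from all genes. The called members of the lists moved with single libraries as the whole count did. The tool and the scaling moved them too. DESeq2 called 6 furrow collagens higher and limma-voom 0, and DESeq2 called 44 cuticle collagens higher and 18 lower, 34 molting and apical matrix genes and 15 hedgehog-related genes higher, and 14 proteasome genes lower. edgeR called 6 oocyte and eggshell genes lower. With library size alone, which moves most genes up, limma called 33 molting and apical matrix genes, 22 FMRFamide-like neuropeptides, 14 neurons genes, 24 sperm and major sperm proteins, 25 nuclear hormone receptors, 11 glucuronosyltransferases, 10 hedgehog-related, 9 cuticle damage and osmotic response, 8 heterochronic and molt timing and 4 lysozymes and saposin-like genes higher, and none of the falls in epidermal antimicrobial peptides, seam and epidermis and C-type lectins was called. Leaving out mutant library 3 raised the members called higher to 43 in molting and apical matrix, 51 in cuticle collagens, 18 in hedgehog-related, 17 in FMRFamide-like neuropeptides, 12 in neurons and 12 in epidermal antimicrobial peptides. It raised those called lower to 24 in oocyte and eggshell, 26 in germline and meiosis and 29 in proteasome. Leaving out any other library left no call by limma in oocyte and eggshell, germline and meiosis, proteasome, neurons, furrow collagens, collagen processing enzymes, heterochronic and molt timing, distal tip cell migration, pharynx and mitochondrial respiration. Without wild-type library 1, 2 or 3 and without mutant library 1 or 2, limma called 8, 8, 7, 4 and 3 epidermal antimicrobial peptides higher and 5, 3, 2, 1 and 1 molting and apical matrix genes higher. In the same order, limma called 1, 0, 0, 0 and 0 FMRFamide-like neuropeptides and 1, 0, 2, 0 and 0 hedgehog-related genes, all higher. For those fits, cuticle collagens had 6, 2, 6, 1 and 1 members called higher and 7, 3, 5, 4 and 4 called lower.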

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

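The threshold of 0.01, the pseudocounts, TPM, edgeR on the recovered reads as an alternative, its filter and its block, the oocyte covariate, the removal of ribosomal RNA or of both replicate-1 libraries and leaving out libraries with edgeR and DESeq2 were chosen after seeing the data. Against 3061 calls (1216 higher, 1845 lower, 1135 at least 2-fold), no filter on low values gave 115 (96 higher, 19 lower, 115 at least 2-fold), over 22878 genes, and the cause was not tested. A threshold of 0.01 gave 38 (31, 7 and 38). Without both replicate-1 libraries there were 116 (95, 21 and 116). With each library left out in turn, over limma, edgeR and DESeq2, calls ran from 38 to 5770, higher calls from 29 to 2267, lower calls from 9 to 3562 and those at least 2-fold from 38 to 3451. DESeq2 gave 326 to 5770, edgeR 50 to 5257 and limma 38 to 5077. Fewer libraries leave fewer degrees of freedom, yet leaving out mutant library 3 raised the count. Library size alone gave 2282 higher, 140 lower and 1812 at least 2-fold, upper-quartile scaling gave 2032 higher, and TPM gave 2402 higher and 349 lower, since these scalings move all genes up together. DESeq2 gave 1718 at least 2-fold, and pseudocount 2 gave 758 at least 2-fold, which stayed within 1.5 times of the main count.

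The replicate numbers share no stated origin. Deviations from the group means correlated at 0.35, 0.44 and -0.09 between the libraries of numbers 1, 2 and 3. Between a wild-type and a mutant library of different numbers they correlated at -0.45 to 0.19. A shared origin of the libraries of number 1 or of number 2 is therefore not excluded, and the main fit did not pair the libraries. With the replicate number as a block, limma called 5877 (2372 higher, 3505 lower) and edgeR 5512 (2094 higher, 3418 lower, 1865 at least 2-fold). The log2 values of each mutant library correlated best with wild-type library 3 among the wild-type libraries (0.936, 0.932 and 0.978).

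With the oocyte level as a covariate limma called 1 gene, *col-124* (0 higher, 1 lower, 1 at least 2-fold), with 329 at an unadjusted p under 0.05. Those 329 are a share under 0.05 of the 13756 tested genes, so they are no sign of remaining signal. The covariate follows the group closely and leaves 3 residual degrees of freedom in place of 4, and the median SE went from 0.26 to 0.42. Of 121 called named genes, 33 had under 0.5 of their fold with the covariate, 37 had 0.5 to 0.8 of it and 51 had 0.8 or more, with a median of 0.734. Among those that shrank, *mex-6* went from -1.36 to -0.11 (SE 0.30), *chs-1* from -1.45 to -0.21 and *grl-4* from 1.44 to 0.65. Among those that did not, *col-176* went from 4.14 to 4.12 (SE 0.77), *cnc-2* from 2.66 to 2.87 (SE 0.47) and *col-139* from -2.12 to -3.07 (SE 0.38), and their calls ended with the wider SE and the lower degrees of freedom. The medians of molting and apical matrix (0.96 to 0.41), germline and meiosis (-0.87 to -0.25) and FMRFamide-like neuropeptides (0.77 to 0.42) shrank. Those of epidermal antimicrobial peptides (1.64 to 0.72), furrow collagens (1.85 to 0.65), cuticle damage and osmotic response (0.80 to 0.45) and heterochronic and molt timing (0.59 to 0.29) shrank too. The medians of cuticle collagens (-0.22), hedgehog-related (0.0863), fungus-induced peptides (-0.58), oocyte and eggshell (-0.0148) and pharynx (-0.11) then carried a camera direction opposite to before, where that of oocyte and eggshell was set by the covariate, which is that list's own mean. Among lists not called before, the medians of early zygotic embryo (-0.47 to 0.43), adult cuticle collagens (0.19 to -0.57), lysozymes and saposin-like (0.16 to -0.17), F-box and MATH/BTB (0.08 to -0.17), fatty acid desaturation and synthesis (0.08 to -0.03) and autophagy and lysosome (0.01 to -0.08) changed sign. With the covariate, camera at the preset correlation called 24 lists. The estimated correlation and fry were run on the main fit alone, where each called 0 lists.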

Other observations

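Of 25 histone genes, 7 fell, among them *hil-5* (-1.19), *his-38* (-1.06) and *his-68* (-1.02), and *his-70* (1.13) and *his-3* (0.97) rose, whereas with library size alone 1 of the histones fell and 3 rose. Adjusted over the list alone, 9 fell and 2 rose (camera adjusted p = 0.119). Of 139 F-box and MATH/BTB genes, 5 rose and 16 fell, 2 and 7 adjusted over the list alone, whereas with library size alone 8 of the F-box and MATH/BTB list rose and 2 fell. Its median was 0.08, its mean -0.05 and its camera direction lower, with *fbxa-24* at 1.55, *fbxc-49* at 1.11, *fbxc-50* at -1.25 and *fbxa-215* at -1.28 (camera adjusted p = 0.640). Of 19 genes of the insulin and DAF-16 response, *lys-7*, *mtl-1* and *sodh-1* (68.2 ± 9.61 to 163 ± 41.6 CPM) rose and *sod-3*, a superoxide dismutase (-1.01), *age-1* (-0.86) and *daf-18* (-1.18) fell, also adjusted over the list alone (camera adjusted p = 0.436), whereas 5 of the insulin and DAF-16 response list rose and 1 fell with library size alone, and 5 rose and 2 fell with TPM. Of 5 genes that DAF-16 represses, *dod-23* and *dod-24* fell, at -1.34 and -1.13 (2 adjusted over the list alone, camera adjusted p = 0.230). The DAF-16 repressed (dod) median of -0.21 turned to 0.09 with library size alone and 0.04 with TPM.

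Of 28 chaperones, *sip-1* (-0.90), *cct-8* (-0.82) and *hsp-60* (-0.77) fell, and 0 passed when adjusted over the list alone (camera adjusted p = 0.102). With library size alone and with TPM, 1 of the heat shock chaperones rose and 0 fell. Of 40 nuclear genes of mitochondrial respiration, *sdha-2* (-0.86), *cox-11* (-0.81), *ucr-2.3* (-0.83) and *cox-15* (-0.70) fell and *cyc-2.2* rose (0.85), 4 and 1 adjusted over the list alone. The median for mitochondrial respiration was -0.25 and turned to 0.08 with library size alone and 0.02 with TPM (camera adjusted p = 0.0129, and adjusted p = 0.631 with an estimated correlation). Of 12 mitochondrially encoded genes *ndfl-4* fell (-0.73), with 0 adjusted over the list alone (camera adjusted p = 0.355), and the mitochondrially encoded median of -0.115 turned to 0.22 with library size alone, 0.15 with TPM and 0.02 with upper-quartile scaling. Of 34 glutathione transferases *gst-24* (0.82) and *gst-31* (0.79) rose, of 25 genes of fatty acid synthesis *elo-4* rose (1.08), and of 48 autophagy and lysosome genes *lgg-3* (-0.88), *cup-5* (-0.79) and *vha-18* (-0.88) fell, each with 0 adjusted over the list alone (camera adjusted p = 0.124, 0.211 and 0.361). With upper-quartile scaling, library size alone and TPM, 5, 8 and 7 glutathione transferases and 3, 2 and 3 genes of fatty acid desaturation and synthesis rose. The autophagy and lysosome median was 0.01, its mean -0.10 and its camera direction lower, and with library size alone and with TPM 2 of its members rose and 0 fell. Of 57 genes of lipid breakdown *lipl-6* rose (0.425 ± 0.410 to 3.29 ± 2.38 CPM) and *acdh-2* and *lbp-9* (-0.70) fell, with 0 and 1 adjusted over the list alone (camera adjusted p = 0.223). For lipid breakdown, 7 rose and 1 fell with upper-quartile scaling and with library size alone, and 8 rose and 1 fell with TPM.

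The tests below on scaling, on stage, on other collagens, on *col-124* with a covariate and on mutant library 3, and the other splits, were chosen only after the results they bear on had been seen. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 3061 calls, 1216 higher, 1845 lower and 1135 at least 2-fold, and the highest other split gave 0 in each count by limma, with up to 1396 genes at an unadjusted p under 0.05. For called lists the real split gave 23 and the highest other 21. Every other split mixes both genotypes within each of its groups. Its residual spread then holds the genotype difference, so the counts of 0 do not give a chance level.

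In the mutant 16 of 26 oocyte and eggshell genes fell and 19 of 58 molting genes rose, with medians 2.36 apart on the log2 scale (both lists with adjusted p = 0.576 with an estimated correlation, and 0.126 and 0.0903 by fry). Scaling between libraries does not account for this, as under each of 4 scalings the molting median stayed at least 0.94 above 0 and the oocyte median at -1.07 or lower, nor do the shallow replicate-1 libraries, without which the difference was 1.91. Mutant animals at an earlier stage, or with fewer oocytes, may account for it. Across genes, which are not independent replicates, the slope on the oocyte level within mutant libraries and the fold change with its sign turned had a Spearman correlation of 0.79 (-0.02 within wild-type libraries, where the oocyte level spanned 0.25 on the log2 scale against 1.55), but any cause of a weaker shift in mutant library 3 would give this too, so it does not bear on stage. Stage at harvest and an effect of the mutation on the tissues cannot be told apart with these libraries.

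With the oocyte level as a covariate the fall of *col-124* was -6.64 (SE 0.31) against -6.42 (SE 0.20) without it, and the 10 nearest tested genes that do not overlap it had a median of 0.38 (the overlapping *qns-1* stood at -0.42), which argues against oocyte content and against loss of a wider segment. No single collagen took up the reads, since the next rise, that of *col-42*, named after its values were seen, was 0.156 of the fall. The rises of all other collagens summed to 1.43 times the fall, while all collagens together went from 5.54% to 4.55% of the reads and the cuticle collagens list lay at -0.31 in mutant library 3, so reads spread over several collagens stay open, a split of that question made after the values were seen. A change within the *col-124* gene itself in the mutant strain, or regulation by BLMP-1, was not tested.

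Mutant library 3 lay nearer to wild type than the other mutant libraries, with a median of 0.467 of their shift over the genes called lower and 0.681 over those called higher. Wild-type animals or RNA in that library do not account for it, since *col-124* stood at 1.02% of its wild-type level there, where the oocyte level would need a wild-type share of 58.9%. A later stage of that library may account for it: 87.9% of the molting genes were lower there than in both other mutant libraries while those lay above wild type, but the list's mean had been seen beforehand. Among genes above wild type in both other mutant libraries, 89.5% of 57 molting genes and 69.1% of 6391 others were lower in mutant library 3, so most of this goes with the weaker shift of that library as such and adds little for stage. The labels name no biological difference for this library.

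Within 2 Mb of *blmp-1*, 27.7% of 649 tested genes were called, 1.26 times the share elsewhere (Fisher's exact test, two-sided, p = 0.00084) and 1.15 times that on the rest of chromosome I (p = 0.0697 by the same exact test, chosen after the values were seen). The exact test takes genes as independent, which they are not, so its p-values do not measure the spread between libraries. X-linked genes had a median log2 fold change 0.23 above that of autosomal genes, and 0.17 above it with the oocyte level as a covariate. The autosomes differed among themselves, so the higher median was not particular to X. It was 0.233 on X, 0.218 on V, 0.118 on IV, 0.00987 on II, -0.245 on I and -0.251 on III. There were 142 higher and 62 lower calls on X and 1072 and 1782 on autosomes. The share of tested genes called lower was smallest on X, 3.29%, against 11.7% on V, the next smallest. In a scan over 110 gene families by name, chosen after the data were seen, camera called 52, and with an estimated correlation the lowest adjusted p was 0.598.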
